A study of Mus musculus with 9 samples.

How the data were processed

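ATAC-seq was carried out on D2A1-d cells transduced with a non-targeting control or with a hairpin against Med4, with 3 libraries for each of NTC, shMed4 #1 and shMed4 #4. The deposited values are signal per peak: normalised read counts in a common set of 146,734 peaks, made by the authors with DESeq2 per the name of the deposited file. The submitters' processing notes name Trim Galore, BWA, MACS2, featureCounts and Subread, without versions, and the builds mm10 and GRCm38. Whether peaks were called per library or on pooled reads is not given in the sources used here. All values of each column were whole multiples of a single step (100% within 0.0001 of a read). The whole reads behind the deposited values could therefore be recovered as reads per peak before division by a size factor. Libraries held 44.8 to 98.9 M reads in peaks. Coordinates are printed as the deposited peak names give them, and whether they count from 0 is not stated.

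The main test was limma (3.58.1, R 4.3.3), with lmFit and eBayes with a trend on log2 of the normalised value plus 1. The 146,729 peaks with a mean of at least 10 were tested, which removed 5, in 1 fit over 9 libraries with a mean per group. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Contrasts were the mean of both hairpins against NTC, each hairpin against NTC, and hairpin #4 against #1. The p-values measure the spread between these libraries, whose relation to separate transductions is not given in the sources used here. Pairs of libraries were checked for near-identical values by a chi-square on the recovered reads, and none were merged. Every library was kept.

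The groups, tests, naming rule, 25 gene lists and first set of alternatives were chosen before the data were examined. The naming rule took every peak assigned to Med4. It took the 12 highest and 12 lowest log2 folds among peaks called with both hairpins in the same direction, and the 5 highest and 5 lowest calls of each other comparison. Peaks needed a mean of at least 50, 1 peak was taken per gene, and predicted genes were left out. For each list it took the 3 members with the lowest p. Genes named outside the rule are said to be so, and 2 that it took are not reported here. The design called for promoters. Because the gene table used has no strand, peaks within 1 kb of either end of a gene were used in their place, a departure from the design. Of the 21,631 protein-coding genes used, 13,064 had such a gene-end peak, 70.2% of them at 1 end only, and 2,830 of the 18,548 gene-end peaks served more than 1 gene. With peaks at both ends, the peak with the highest mean was taken. Other peaks were assigned to the nearest gene within 100 kb, a convention and not a measured target. Exons, introns and untranslated regions were not analysed here. Of 936 genes written in the lists, 934 were found in the gene table.

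Lists of at least 5 genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it, and adjusted over the lists. Members called were counted over all peaks and adjusted over the list alone. Overlap between hairpins was set beside the product expected of independent lists. It was also set beside 20 simulations of unchanged groups, in which both comparisons shared the same simulated NTC group. Gene-end and other peaks were compared by an exact permutation test over 84 splits of library means. The difference was also taken at like height in 50 bins, without a test. Regional medians were taken over 225 windows of 10 Mb, with 10,000 permutations. Groups of libraries were regrouped in 100 draws of 840 possible splits, or in all 10 where 6 libraries were compared.

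The pipeline was tested on simulated data with the spread of these libraries. Of 50 peaks changed at each size, 36% were called at 1.25-fold, 64% at 1.5-fold and 100% at 2-fold and 4-fold, and 0.003% of unchanged peaks were called. So few changed peaks make the adjusted threshold stricter than in the real data, where 54.1% of peaks were called for shMed4 against NTC. These shares therefore do not give the power of the main test. A list of 30 genes raised 1.3-fold was called, and 0 of 24 unchanged lists were. The simulated peaks were independent of each other, whereas random regroupings of the real libraries called up to 8 lists. The alternatives changed the pseudocount, filter, scaling, threshold, test and fit, and left out each library in turn. edgeR 4.0.16 and DESeq2 1.42.0 were run on recovered reads as alternatives only. Removal of regional shifts, centring on gene-end peaks, thinning to the shallowest library and lists without shared genes were added after the data had been seen. Motif and GC content tests were planned but need a genome sequence, which was not used here. Values were handled with the data.table package (version 1.17.8), numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.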

Results

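Chromatin accessibility was measured by ATAC-seq in D2A1-d cells, a mouse breast carcinoma line, that carried a non-targeting control hairpin (NTC) or a short hairpin RNA against Med4. ATAC-seq uses a transposase that inserts sequencing adapters into open chromatin, so the reads in a peak report how accessible that stretch of DNA was. Med4 encodes a subunit of the middle module of Mediator, the complex that links transcription factors at enhancers and promoters to RNA polymerase II. There were 3 groups of 3 libraries each: NTC, shMed4 #1 and shMed4 #4, which carried different hairpins. The study's title places MED4 in the control of metastatic dormancy, and the comparisons ask which regulatory regions opened or closed when it was depleted. Values were normalised read counts in 146,734 peaks of equal width, placed on the GRCm38 (mm10) assembly. Between 44.8 and 98.9 M reads fell in peaks per library, with a median of 110 to 247 reads per peak. On simulated data with the same spread and 50 peaks changed at each size, 100% of peaks changed 2-fold were called and 64% of those changed 1.5-fold. With so few changed peaks the adjusted threshold is stricter than in the comparisons below, so these shares do not give their power.

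Libraries of a group resembled each other closely and the 3 groups stood apart. Over all peaks, the chi-square per degree of freedom between libraries of the same group was 1.99 to 2.92, against 9.96 to 29.06 between libraries of different groups. No pair of libraries agreed within sampling noise, so all 9 were counted separately. The first principal component carried 54.4% of the variance and parted the NTC libraries from the 6 shMed4 libraries. The second carried 27.6% and parted the hairpins from each other.

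The Med4 locus itself changed little. The peak at the end of Med4, at chromosome 14, 73509724 to 73510225, spans the end of the annotated gene, with its centre 75 bp outside. It held 544 ± 24.2 normalised reads in NTC (mean ± SD, n = 3 per group here and below). It held 451 ± 23.5 with hairpin #1 and 469 ± 21.4 with hairpin #4, a log2 fold of -0.24 (SE 0.06, limma adjusted p = 0.0017) over both hairpins. The peak inside Med4 at 73510689 to 73511190 was weak and was not called (log2 fold -0.12, SE 0.20). Of the 4 other peaks nearest to Med4, all outside the gene, the peak at 73449072 to 73449573 rose, from 137 ± 5.8 in NTC to 279 ± 9.1 and 236 ± 25.2 (log2 fold 0.90, SE 0.09). Hairpins act on the transcript, so accessibility does not measure the depletion, and these peaks do not check the labels.

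The first comparison set both hairpins together against NTC and asked which regions changed on Med4 depletion. Peaks at least 2-fold higher had few reads in NTC, with a median of 61 against 184 over all tested peaks. Among peaks with a mean of at least 50 and a named nearest gene, called the naming limits below, the largest rise called with each hairpin was inside Ust, which encodes a sulfotransferase of the glycosaminoglycans chondroitin and dermatan sulfate. That peak, at chromosome 10, 8506244 to 8506745, rose from 29.2 ± 5.9 normalised reads in NTC to 846 ± 51.6 with hairpin #1 and 536 ± 63.3 with hairpin #4 (log2 fold 4.50, SE 0.10, limma adjusted p = 1.5e-29). A peak inside Sash1, a signalling scaffold gene about 0.3 Mb away on the same chromosome, rose from 16.3 ± 5.2 to 309 ± 14.8 and 322 ± 19.9 (log2 fold 4.24, SE 0.15, limma adjusted p = 6e-24).

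Other strong gains lay inside genes of varied function. A peak inside Suclg2, the mitochondrial succinyl-CoA ligase subunit, at chromosome 6, 95511105 to 95511606, had a log2 fold of 4.09 (SE 0.11). Slc44a1, a choline transporter, had a peak at chromosome 4, 53539401 to 53539902, with a log2 fold of 4.03 (SE 0.10). Rbms3, which encodes an RNA-binding protein, held a peak at chromosome 9, 116592461 to 116592962, that rose from 47.5 ± 8.8 to 613 ± 18.6 and 880 ± 57.2 (log2 fold 3.94, SE 0.09). Zfp536, a zinc finger repressor of neuronal genes (3.82), Dip2a (3.70), Brinp3, a neural gene induced by retinoic acid (3.62), Fryl (3.59) and Flrt2, a cell adhesion gene (3.57), each held a raised peak within the gene body. The peak nearest to the nucleoporin gene Nup88 lay inside Rabep1, an endosomal transport gene, and rose by 3.56. The Sash1, Rbms3, Brinp3 and Flrt2 peaks each lay in a stretch of at least 20 consecutive peaks that all rose with both hairpins. The median NTC values of those stretches were 17.1, 18.7, 20.5 and 24.2, under the first percentile of all tested peaks (25.2). The Zfp536 peak also lay in such a stretch, of 30 peaks, with a median NTC value of 50.5, above the fifth percentile (44.8).

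Falls were smaller. The strongest, within the same limits, was at chromosome 12, 110244559 to 110245060, 34421 bp from Dio3, the deiodinase that inactivates thyroid hormone. It went from 365 ± 27.8 normalised reads in NTC to 33.6 ± 8.5 with hairpin #1 and 106 ± 16.1 with hairpin #4 (log2 fold -2.61, SE 0.15, limma adjusted p = 1.6e-17). A peak inside Sqor, which encodes the mitochondrial sulfide oxidase, fell from 132 ± 2.5 to 19.3 ± 3.4 and 24 ± 3.8 (-2.57, SE 0.23). A peak inside the integrin gene Itga8 at chromosome 2, 12174669 to 12175170, fell from 161 ± 11.9 to 14.7 ± 4.3 and 60.7 ± 6.7 (-2.40, SE 0.20). Peaks near Tsku, a secreted proteoglycan gene (-2.27), and near Nampt, the rate-limiting enzyme of NAD salvage (-2.20), also fell. So did peaks inside Cobll1 (-2.17), Trappc10 (-2.10), Adgb (-2.08), Gas7 (-2.00) and Lrrc9 (-1.95). The list closed with peaks outside Tle3, a Groucho corepressor gene (-2.07), and outside Tnfaip3, the inhibitor of NF-kB signalling known as A20 (-1.97). Sqor, Itga8 and Cobll1 lie on chromosome 2, and Dio3, Nampt and Lrrc9 on chromosome 12. Gene-end peaks of those chromosomes had median log2 folds of -0.39 and -0.33 with hairpin #1, and of -0.22 and -0.23 with hairpin #4.

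**Figure D1:**
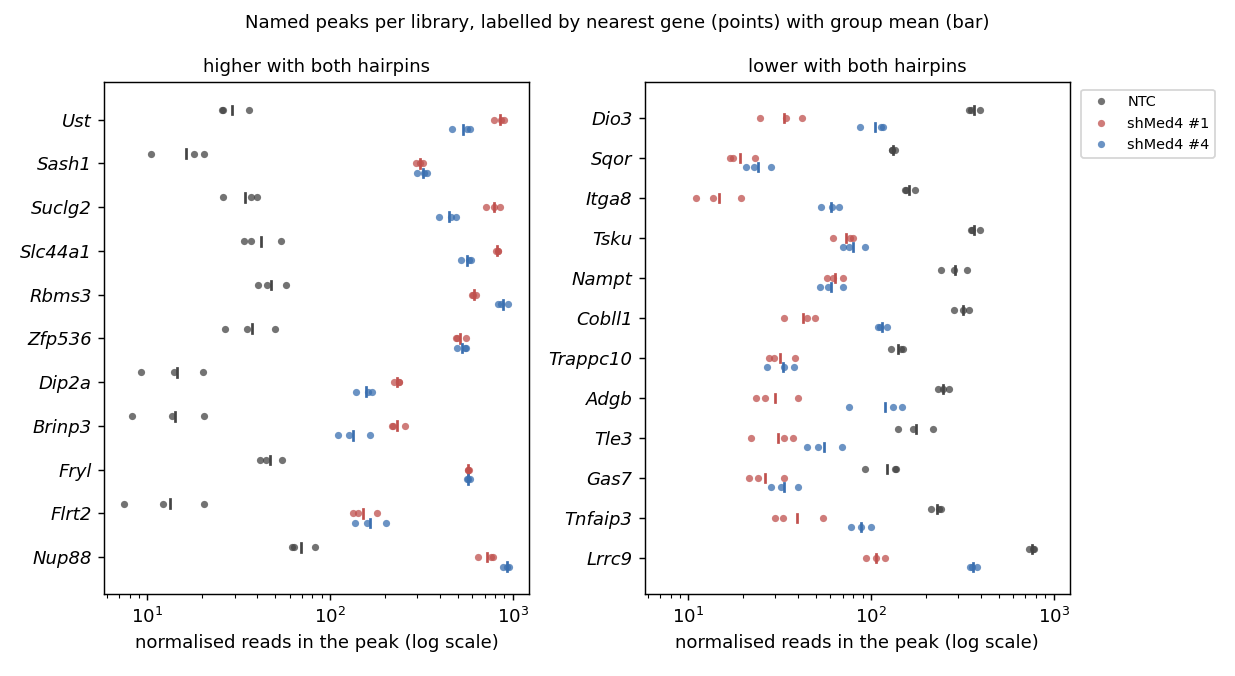
Normalised reads (log axis) in the named peaks that rose most and that fell most with both hairpins, labelled by nearest gene; points are libraries and bars are group means of 3 libraries. At the Ust peak the NTC mean is 29.2 and the hairpin means are 846 and 536; at the Dio3 peak they are 365, 33.6 and 106.

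In all, 79,398 of the 146,729 tested peaks (54.1%) differed between shMed4 and NTC, 40,936 higher and 38,462 lower. This contrast is the mean over the hairpins, so it also calls peaks changed with 1 hairpin or in opposite directions. The Olfr121 peak, for one, was called with log2 folds of 1.93 with #1 and -0.53 with #4. In the comparisons of each hairpin alone, 45,629 peaks were called with both in the same direction. Large changes were mostly gains: 8,767 peaks were at least 2-fold higher and 1,409 at least 2-fold lower. The peaks at least 2-fold higher had a median of 185 normalised reads in the shMed4 libraries. Of these, 51.5% lay inside a protein-coding gene, against 52.7% of all tested peaks, and they lay a median of 36.5 kb from the nearest gene end, against 17.3 kb. The split of small changes depends on how libraries are scaled: 36.9% of calls were higher when libraries were centred on peaks away from gene ends and 62.7% when centred on gene-end peaks, against 51.6% as reported.

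Peaks at gene ends shifted down as a class. A gene-end peak is here a peak within 1 kb of either end of a protein-coding gene, since gene strands were not used. Such peaks made up 12.6% of tested peaks, 5.8% of higher peaks and 19.2% of lower peaks, and 2,389 of them rose while 7,392 fell. Among changes of at least 2-fold they made up 5.2% of higher and 6.3% of lower peaks, both under 12.6%. Of all gene-end peaks 2.46% rose and 0.48% fell at least 2-fold, against 6.48% and 1.03% of other peaks. The excess among lower peaks therefore came from smaller changes. The median log2 fold of gene-end peaks was -0.12, against 0.01 for all other peaks. The difference between the medians was -0.12 over all peaks and -0.13 among peaks of like height. In both, each of the 6 shMed4 libraries lay below each of the 3 NTC libraries. The difference not matched for height was tested (exact permutation test over 84 splits, two-sided p = 0.0119, the smallest it can give). Libraries of a group resembled each other closely, so this test excludes a random division of the libraries only. It cannot exclude chance differences between the 3 groups of cells. The library values of the tested difference, centred over all libraries, were 0.066 to 0.104 in NTC and -0.12 to 0.008 with the hairpins. Centred on gene-end peaks, which brings their own median near 0 by construction, 4,967 of them still fell and 3,125 rose.

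Medians also differed by chromosome. With hairpin #1 the median log2 fold of gene-end peaks was -0.39 on chromosome 2, -0.33 on chromosome 12 and -0.25 on chromosome 18, against 0.01 on chromosome 1 and -0.03 on chromosome 6. With hairpin #4 the chromosome 2 and 12 medians were -0.22 and -0.23, and those of chromosomes 6 and 15 were -0.01. Chromosomes 10, 13 and 11 were about as low with #4 (-0.22, -0.21 and -0.20), against -0.09, -0.12 and -0.15 with #1. Peaks away from gene ends moved in parallel, with medians of -0.29 and -0.15 on chromosome 2 for hairpins #1 and #4. Many small falls at single genes named below lie on chromosome 2. Genes on chromosome 12, where gene-end medians were also low with both hairpins, are not marked as such below.

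**Figure D2:**
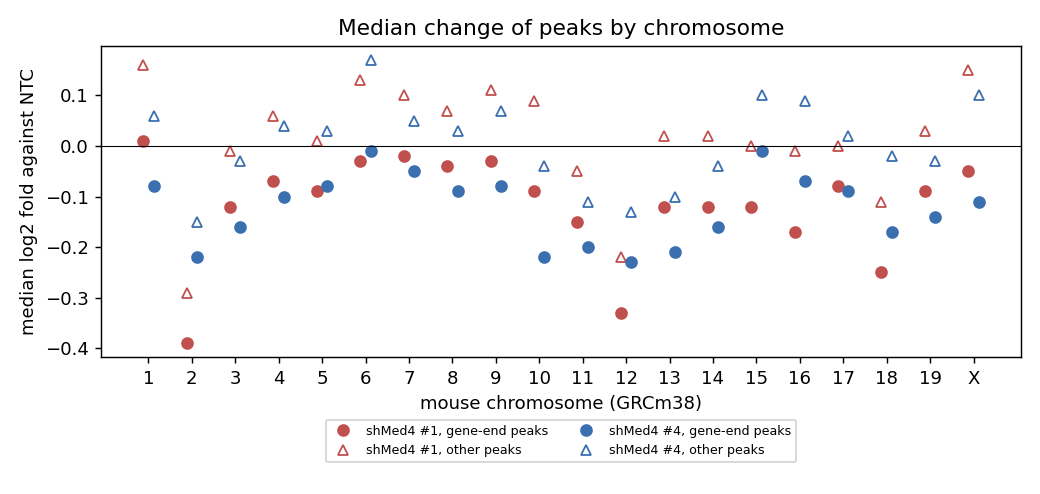
Median log2 fold against NTC of gene-end peaks (circles) and all other peaks (triangles) on each mouse chromosome, for each hairpin. Chromosome 2 is lowest with hairpin #1, at -0.39 for gene-end peaks and -0.29 for other peaks.

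Gene groups fixed in advance were read at 1 gene-end peak per gene. Counts of members called are over all peaks, and adjusted over the list alone they were the same unless given. Some peaks lie at the ends of a pair of genes and cannot be given to either: those named below for Aurka (with Cstf1), Pcna (Cds2), Med31 (4930563E22Rik), Ifit1 (Ifit1bl2), Zfp36l1 (Gm52006), Sesn1 (Cep57l1), Pfkl (Cfap410), Rpl12 (Lrsam1), Cd4 (Gpr162), Nos3 (Atg9b), Pdgfrb (Gm52351) and Grin1 (Lrrc26), besides those said to be shared. Over all 13,063 genes with such a peak, 11.6% rose and 43.4% fell, with a median log2 fold of -0.11, and camera compared each list with that background. Epithelial genes stood above it. Of 18 measured members 7 rose, among them Pkp1, a plakophilin of desmosomes (103 ± 19.6 reads in NTC, 577 ± 72.9 and 577 ± 69.2 with the hairpins; log2 fold 2.49, SE 0.09), the simple-epithelial keratin Krt18 (1.33, SE 0.08), the tight junction genes Cgn (0.84) and Cldn1 (0.74), and Jup, encoding plakoglobin (0.60). Another 6 fell, including the protease gene St14 (-0.53) and the splicing regulator Esrp2 (-0.25). Cgn, Cldn1, St14 and Esrp2 were picked after their values were seen. The camera adjusted p was 0.00361 (upward), and the adjusted p with an estimated correlation was 0.157. The median of the list was 0.05 and its mean 0.29. The median was -0.05 when libraries were centred on peaks away from gene ends and 0.11 when centred on gene-end peaks, and such centring moves all genes alike. Luminal and myoepithelial markers, a list that shares 6 of its 11 measured genes with other lists, had 5 higher and 3 lower members (camera adjusted p = 0.0294, and adjusted p = 0.235 with an estimated correlation). Acta2, the smooth muscle actin (2.19, SE 0.07), Krt18 and Krt14 (0.79, SE 0.06) rose, and the list's median (-0.08) and mean (0.31) differed in sign. This list was not called with cyclic loess or with the mean of all gene-end peaks of a gene. With genes that appear in more than 1 list removed, the adjusted p was 0.0705 for epithelial genes and 0.501 for the luminal and myoepithelial list. In 100 random regroupings of the 9 libraries up to 8 lists were called, against 2 here.

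Matrix, adhesion and contractility genes moved in both directions, and camera called none of these lists. Among collagens and other matrix proteins 7 rose and 10 fell of 28, with Postn, encoding periostin, higher (0.86, SE 0.07) and the peak shared by the basement membrane collagens Col4a1 and Col4a2 lower (-0.83, SE 0.08). Among matrix remodelling enzymes 7 rose and 14 fell of 32, a balance that depends on the scaling. Centred on gene-end peaks 8 rose and 7 fell, and centred on peaks away from gene ends 4 rose and 20 fell. The peak of the aggrecanase gene Adamts5 rose from 41.4 ± 5.6 to 306 ± 32.2 and 411 ± 43.9 reads (3.07, SE 0.11), whereas the metalloprotease gene Mmp19 (-0.98) and the collagen crosslinking oxidase Lox (-0.86) fell. Lox differed between the hairpins: -1.58 with #1, and -0.14 with #4, which was not called. Of 13 integrins 5 rose and 6 fell, including Itgb3 (1.28), Itga9 (0.74) and Itgb7 (-0.46; -0.84 with #1 and -0.08 with #4). Of 45 focal adhesion and actomyosin genes 6 rose, led by Acta2 and the myosin light chain Myl9 (1.67), and 16 fell, among them the kinase Src (-0.41) on chromosome 2. YAP and TEAD targets had 4 higher and 11 lower of 28 (Amotl1 0.53, Ptpn14 0.38, Fjx1 -0.54). For them too the balance depends on the scaling, with 6 higher and 6 lower centred on gene-end peaks, and 3 and 19 centred away from gene ends. TGF-beta and BMP signalling genes had 4 higher and 18 lower of 36 (4 and 19 adjusted over the list alone), with Id1 (-0.33), Smad4 (-0.31) and Ltbp2 (-0.29) lower. Mesenchymal genes had 4 higher and 9 lower of 17, with a median of -0.13 and a mean of 0.12, where Acta2 rose and Vim, encoding vimentin (-0.43), and the transcription factor Snai1 (-0.36), both on chromosome 2, fell.

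Among genes linked to dormancy 3 rose and 10 fell of 26. The endoplasmic reticulum chaperone Hspa5 (-0.36) and the glycolysis regulator Pfkfb3 (-0.38), both on chromosome 2, fell and the circadian repressor Bhlhe40 rose (0.34). Their median was -0.06, and 0.01 when libraries were centred on gene-end peaks. Mammary stem and Wnt pathway genes had 8 higher and 14 lower of 32 (8 and 15 adjusted over the list alone), and their median (-0.13) and mean (0.05) differed in sign. The peak of the Wnt receptor gene Fzd6 rose from 69.6 ± 13.8 to 339 ± 29.6 and 383 ± 49.0 reads (2.37, SE 0.11), while the repressor Tcf7l1 (-0.77) and the surface marker Cd24a (-0.69) fell. Camera called neither list.

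Housekeeping and proliferation lists had small falls at many genes, and camera called none of them as reported, but some under other settings. Of 48 cell cycle and E2F genes 32 fell and 0 rose, and 33 and 0 adjusted over the list alone (limma calls, camera adjusted p = 0.0935). Those that fell included the mitotic kinase gene Aurka (-0.42), the replication clamp gene Pcna (-0.40) and the phosphatase gene Cdc25b (-0.32), all on chromosome 2. Centred on gene-end peaks, 19 fell and 2 rose. Camera called this list lower than other gene ends with equal totals (adjusted p = 0.043, limma) and with the mean of all gene-end peaks of a gene (adjusted p = 0.025, limma). It was not called with regional shifts removed (adjusted p = 0.195, limma), where 25 fell and 0 rose, with a median of -0.11 against -0.15 as reported. Nor was it called without shared genes (adjusted p = 0.0898, limma), and in the reported fit adjusted p = 0.963 with an estimated correlation. Ribosomal protein genes had 29 lower and 0 higher of 51, with Rpl22 lowest (-0.91, SE 0.07). Rpl12 (-0.30) and Rpl7a (-0.38), whose peak is shared with Med22, lie on chromosome 2 and also fell. With regional shifts removed, 36 of the 51 ribosomal protein genes fell and 0 rose, and camera called the list lower than other gene ends (adjusted p = 0.0109, limma). In the reported fit adjusted p = 0.963 with an estimated correlation. The list was also called with the mean of all gene-end peaks (adjusted p = 0.025, limma), but not with equal totals (adjusted p = 0.188, limma) or without shared genes (adjusted p = 0.326, limma). SWI/SNF and Polycomb subunits had 27 lower and 0 higher of 45, with Pcgf5 falling most (-1.12, SE 0.08), and Dpf3 (-0.32) and Jarid2 (-0.30) by less. Centred on gene-end peaks, 17 ribosomal and 16 SWI/SNF and Polycomb genes fell and 2 of each rose. Of 31 Mediator subunit genes 16 fell and 1 rose (17 and 1 adjusted over the list alone), among them Med22 (-0.38), Med6 (-0.33) and Med31 (-0.23). Of 13 Hox genes 6 fell and 0 rose, with the peak shared by Hoxa5 and Hoxa6 at -0.23.

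Stress and signalling lists held small falls and a few large changes. Hypoxia and glycolysis genes had 20 lower and 1 higher of 37 (21 and 1 adjusted over the list alone). The Pgk1 peak, at chromosome X, 106186727 to 106187228, was the highest gene-end peak in NTC and fell from 10895 ± 488.1 to 4934 ± 262.0 and 4355 ± 376.8 reads (-1.23, SE 0.04, limma adjusted p = 1.8e-23). The 8 other peaks within 20 kb of it had log2 folds of -0.62 to -0.20. Pfkl, encoding phosphofructokinase, also fell (-0.85, SE 0.14). NF-kB and inflammatory genes had 24 lower and 4 higher of 41, with the chemokine Ccl2 (-0.54) and Cebpb (-0.59) lower and the apoptosis inhibitor Birc3 higher (0.93, SE 0.08). Interferon response genes had 19 lower and 3 higher of 39: Ifit1 fell (-0.70), Oasl2 rose (0.74), and the peak of Gbp2 (-0.40) fell with hairpin #1 (-0.78) while its log2 fold with #4 was -0.01. AP-1 and immediate early genes had 18 lower and 3 higher of 35, with the peak of the phosphatase gene Dusp2 rising from 117 ± 16.5 to 510 ± 28.6 and 545 ± 18 reads (2.17, SE 0.08) and Zfp36l1 (-0.49) and Atf2 (-0.35) falling. Of 36 p53 targets and CDK inhibitors 14 fell and 1 rose (13 and 1 adjusted over the list alone), among those that fell Ddb2 (-0.38), Rbl1 (-0.38) and Sesn1 (-0.33). The median of that list, -0.07, was 0.00 when centred on gene-end peaks. Camera called none of these 5 lists.

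Lists set up in advance as markers of other cell types were not called by camera for both hairpins together, apart from the luminal and myoepithelial list above. Endothelial and fibroblast markers were called with hairpin #4, as given below. Whether these breast carcinoma cells express such genes was not measured. Some, such as Krt18, Acta2 and Postn, are also in the epithelial, mesenchymal or matrix lists, so these lists are no test for foreign cells. Leukocyte markers had 1 higher and 6 lower of 14 (Cd4 0.33, Lyz2 -0.72, Spi1 -0.31). Endothelial markers had 4 higher and 1 lower of 9 (Flt1 1.49, Cdh5 0.55, Nos3 -0.21; limma calls, camera adjusted p = 0.0536). Camera called them upward with regional shifts removed (adjusted p = 0.0109, limma) and with equal totals (adjusted p = 0.043, limma), but not with the mean of all gene-end peaks (adjusted p = 0.196, limma) or without shared genes (adjusted p = 0.0773, limma). In the reported fit adjusted p = 0.296 with an estimated correlation. Fibroblast markers had 2 higher and 2 lower of 10 (Thy1 1.03, Postn 0.86, Pdgfrb -0.27), and neuronal markers 3 higher and 5 lower of 11 (Tubb3 0.29, Map2 -0.81, Grin1 -0.66). Peaks away from gene ends were assigned to their nearest gene. Of the 25 lists, camera called NF-kB and inflammatory genes there, downward: 89 of 434 peaks rose and 185 fell (89 and 186 adjusted over the list alone), with a median of -0.10 (adjusted p = 0.00287, and adjusted p = 0.0893 with an estimated correlation). That call ended when regional shifts were removed (adjusted p = 0.0526).

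**Figure D3:**
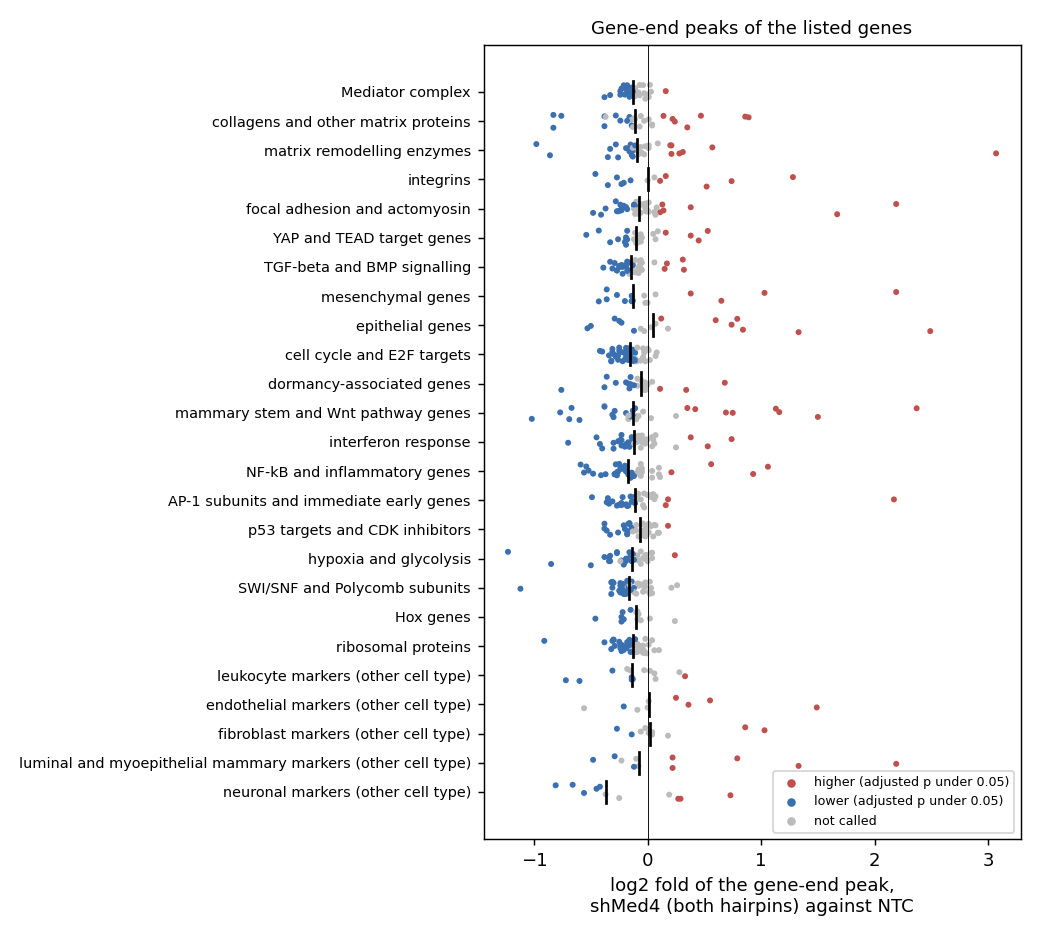
Log2 fold of the gene-end peak of each measured gene (points) in the 25 gene lists, mean of both hairpins against NTC, with the list median as a bar; red and blue mark calls at an adjusted p under 0.05. The epithelial list has 7 higher and 6 lower of 18 genes, and the cell cycle list 0 higher and 32 lower of 48.

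Hairpin #1 alone was then compared with NTC. Within the naming limits (mean of at least 50, named gene) the strongest gains were again at Ust (log2 fold 4.83, SE 0.12), Suclg2 (4.50), Slc44a1 (4.30) and Sash1 (4.21), with a further peak inside Ptprq, a receptor tyrosine phosphatase gene, that rose from 8.9 ± 2.9 to 158 ± 9.2 reads (4.04, SE 0.25). The strongest falls within these limits were at Dio3 (-3.43), Itga8 (-3.40), Adgb (-3.05), the protocadherin gene Pcdh7 (-3.06, SE 0.34) and a second Gas7 peak at chromosome 11, 67523902 to 67524403 (-3.03, SE 0.25). The Pcdh7 peak, inside the gene, fell from 80.8 ± 7.6 to 10.9 ± 8.4 reads with hairpin #1. In all 77,395 peaks differed by limma, 40,871 higher and 36,524 lower, and at least 2-fold 9,588 and 3,779. Camera called epithelial genes (8 higher and 6 lower of 18) and luminal and myoepithelial markers (5 and 3 of 11) upward. The adjusted p was 0.0437 for each, and the adjusted p with an estimated correlation was 0.277 for each. Without replicate 1 of hairpin #1, or without replicate 3 of hairpin #4, camera called 0 lists in this comparison, and without NTC replicate 2 it called 1.

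With hairpin #4 against NTC, within the naming limits, the strongest gain was near Cdk17, a cyclin-dependent kinase gene, from 26.0 ± 3.1 to 541 ± 39.5 reads (log2 fold 4.33, SE 0.16). The same peak reached 113 ± 29.4 reads with hairpin #1. Sash1 (4.27), Rbms3 (4.20) and Ust (4.16) followed, with a peak outside the sulfate transporter gene Slc13a1 (4.06, SE 0.11). The lowest folds were at Sqor (-2.42), Nampt (-2.23), Tsku (-2.21), Trappc10 (-2.08) and a peak 33404 bp from Fth1, the ferritin heavy chain gene, which fell from 581 ± 61.0 to 151 ± 26.3 reads (-1.95, SE 0.11). In all 74,006 peaks differed by limma, 38,417 higher and 35,589 lower, and at least 2-fold 10,454 and 1,353. Camera called 4 lists upward: epithelial genes (adjusted p = 0.000667, and adjusted p = 0.0979 with an estimated correlation), luminal and myoepithelial markers (0.0292 and 0.234), endothelial markers (0.0316 and 0.267) and fibroblast markers (0.0316 and 0.766). Of the 9 endothelial markers 4 rose and 1 fell, and of the 10 fibroblast markers 4 rose and 2 fell. With the replicate number as a block 2 of these lists were called, epithelial genes and the luminal and myoepithelial markers. Without replicate 1 of hairpin #4, 1 list was called.

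Whether the hairpins acted alike was asked from their overlap. Each raised the peaks at Ust, Sash1, Suclg2, Rbms3 and Zfp536 at least 12-fold over NTC and lowered those at Sqor, Tsku, Nampt and Trappc10 to under 1 in 4 of the NTC level. These peaks were picked among those called with both hairpins in the same direction, so their agreement was fixed by the choice. Others picked by the same rule differed in size, such as Itga8 (log2 fold -3.40 with #1 and -1.40 with #4). In all 45,629 peaks were called with both hairpins in the same direction, 25,886 higher and 19,743 lower, and 4,647 in opposite directions. Independent lists of these sizes would share 10,701 higher and 8,859 lower peaks. Simulated unchanged groups with a shared simulated NTC group gave 0. Hardly any call can arise where no peak changes, so that count carries no information on the overlap. At 2-fold or more, 5,875 peaks rose and 510 fell with both hairpins, and 42 went opposite ways. Across peaks, which are not independent replicates, the log2 folds of the hairpins correlated at r = 0.71, against 0.50 for simulated unchanged groups, and 74.0% of peaks had the same sign against 66.7%. The covariance was 0.249 against 0.0108 in the simulation, a difference of 0.238. Both comparisons share 3 NTC libraries, too few to divide, so part of the excess over independent lists may come from them. The simulation holds only the spread within groups. Any difference of the NTC cells from both hairpin lines, whatever its cause, would also raise the overlap, correlation and covariance.

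**Figure D4:**
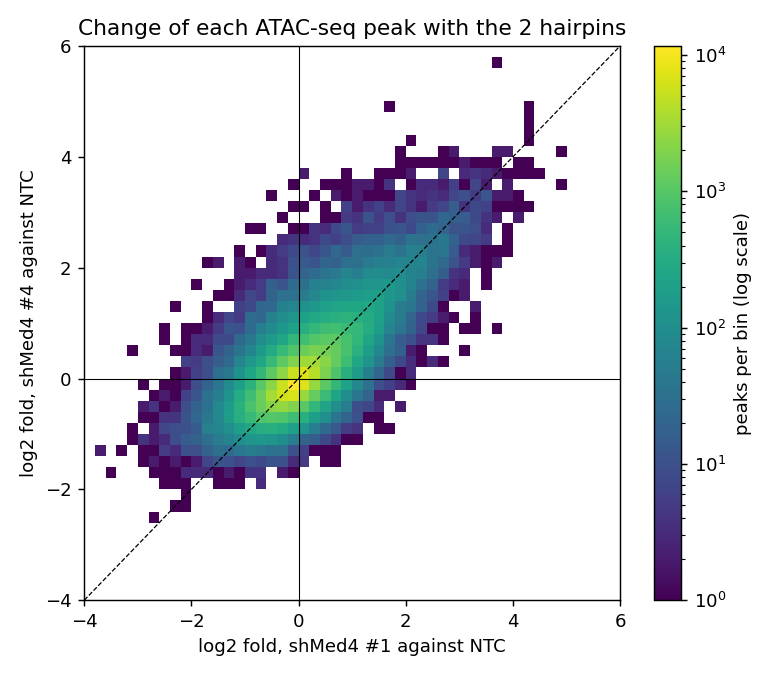
Log2 fold against NTC of each tested peak with hairpin #1 (horizontal) and hairpin #4 (vertical), as peaks per bin on a log colour scale; the dashed line marks equal change. Most of the spread follows the dashed line (r = 0.71 across peaks), and 5,875 peaks are at least 2-fold higher with both.

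The hairpins also differed from each other at many sites. Within the naming limits, the largest excess with hairpin #4 was at chromosome 16, 36463996 to 36464497, 8854 bp from the stefin gene Stfa3: 185 ± 15.6 reads in NTC, 35.5 ± 8.6 with #1 and 460 ± 15.5 with #4 (log2 of #4 over #1 3.68, SE 0.14, limma adjusted p = 8.2e-21). Peaks at Pcdh7 (3.50), Fry (3.06), Ptx3, an innate immune pentraxin (2.93), and Zfp352 (2.89) followed. The Ptx3 peak lay inside Veph1. Hairpin #1 gave more signal inside the laminin gene Lama4 (-2.56), at the end of the olfactory receptor gene Olfr121 (-2.46), outside Spcs3 (-2.37) and inside Afap1, an actin filament gene (-2.34), and Ints4, encoding an Integrator subunit (-2.17). In all 61,001 peaks differed between the hairpins by limma, 29,866 higher and 31,135 lower with #4, and at least 2-fold 4,638 and 1,739. Camera called 0 of the 25 lists at gene ends. The lowest p was that of collagens and other matrix proteins, with 11 higher and 5 lower of 28 (12 and 5 adjusted over the list alone) and a median of 0.10 (camera in limma, unadjusted p = 0.00674, adjusted p = 0.169).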

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

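The tests of the chromosome shifts, of the Pgk1 peak and of copy gain and deletion in the runs below were chosen only after the result was seen. Values that follow were singled out because a direct test of the difference between hairpins passed its threshold. In all 61,001 peaks differed between hairpin #4 and hairpin #1. Log2 differences of #4 minus #1 are given for named peaks.

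Peaks called in opposite directions were those at Olfr121 (-2.46), Afap1 (-2.34), Ints4 (-2.17), Ptx3 (2.93), Fry (3.06) and Stfa3 (3.68). Called with a single hairpin were those at Itgb7 (0.76), Gbp2 (0.78), Lox (1.45), Lama4 (-2.56), Spcs3 (-2.37), Zfp352 (2.89) and Pcdh7 (3.50), and the Med4 peak at 73450159 (-0.48). The Med4 peak at 73510689 was called with neither hairpin and differed by -0.57.

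Among named list genes, the change was larger with hairpin #1 at Cdh5 (-0.61), Postn (-0.56), Amotl1 (-0.47), Krt14 (-0.24), Nos3 (0.13), Id1 (0.17), Src (0.21), Aurka (0.22), Pcna (0.24), Cdc25b (0.25), Cebpb (0.39), Fjx1 (0.46), Grin1 (0.61) and Mmp19 (0.90). The same held for peaks at Ptprq (-1.14), Brinp3 (-0.81), Suclg2 (-0.81), Ust (-0.66), Dip2a (-0.57), Slc44a1 (-0.55), Tle3 (0.82), Tnfaip3 (1.20), Cobll1 (1.42), Dio3 (1.65), Lrrc9 (1.76), Adgb (1.93), Itga8 (2.00) and Gas7 (2.19). Of the list genes, Id1, Src, Aurka, Pcna, Cdc25b, Cebpb, Fjx1 and Grin1 lie on chromosome 2. Gene-end peaks there had median log2 folds of -0.39 with hairpin #1 and -0.22 with #4. A smaller fall with #4 was therefore common to gene ends of that chromosome.

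It was larger with hairpin #4 at Ifit1 (-0.76), Map2 (-0.39), Cd24a (-0.38), the peak shared by Col4a1 and Col4a2 (-0.37), Smad4 (-0.20), Pgk1 (-0.18), Sesn1 (-0.14), Bhlhe40 (0.15), Tubb3 (0.23), Oasl2 (0.24), Krt18 (0.33), Thy1 (0.35), Adamts5 (0.42) and Myl9 (0.67). Peaks at Fth1 (-1.24), Nup88 (0.36), Rbms3 (0.52), Slc13a1 (1.07) and Cdk17 (2.28) completed this set. Cd24a and Sesn1 lie on chromosome 10, where gene-end peaks had median log2 folds of -0.09 with hairpin #1 and -0.22 with #4.

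Medians shifted over large parts of chromosomes, with 73.3% (hairpin #1) and 46.4% (#4) of the variance of 10-Mb windows between chromosomes. If copy number were the cause, strong gene-end peaks and weak other peaks of a 10-Mb window should move together, with r of at least 0.7 for each hairpin. The values were 0.803 and 0.699, so copy number may account for the shifts but was left open by a narrow margin. A trend of fold on peak height was excluded as the whole cause, since the difference between chromosomes 2 and 6 stayed at -0.36 after cyclic loess. Both hairpins against NTC is also the biological contrast, and the data hold no separate measure of copy number. Gene-end medians also stepped within some chromosomes, in the same direction with both hairpins. On chromosome 8 they were -0.184 (#1) and -0.281 (#4) in the window from 100 Mb, and 0.113 and 0.088 from 110 Mb. On chromosome X they were 0.268 and 0.201 from 50 Mb, and -0.136 and -0.232 from 70 Mb. These windows were picked after their values were seen, and the steps were not tested.

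The Pgk1 peak fell by 1.23 on the log2 scale. A Pgk1 promoter is a common part of hairpin vectors, so reads of the vector could add to this peak by different amounts in the groups, but the vector is not given in the sources used here. The 8 other peaks within 20 kb had a median of -0.39, between what such reads and a change of the locus predict. Neighbours with 489 and 1129 reads in NTC had log2 folds of -0.26 and -0.20, and weak ones with 78 to 138 reads had -0.62 to -0.34. The test as set could exclude such reads or leave them open, but could not favour them, so this was left open. A copy number change over most of the 10-Mb window was excluded as the whole cause, since its other gene-end peaks had a median of -0.16. That median cannot exclude a copy number change narrower than the window.

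Long stretches of consecutive peaks rose with both hairpins, in 108 runs of at least 8 peaks, and chance order was excluded, since 100 shuffles gave at most 2 runs. A copy gain in both hairpin lines was left open for the 14 runs with a median log2 fold of at least 2. Folds within them varied with a median chi-square per degree of freedom of 32.65, between the median (15.3) and the 95th percentile (66.0) of 12,191 ordinary stretches of 12 peaks. The median NTC value in them was 24.3, against a first percentile of 25.2 over all peaks, but runs chosen for a high fold over NTC favour low NTC values, so this neither supports nor excludes a deletion in the NTC line. Deletion was left open as well, beside opening of these regions on Med4 depletion.

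The median of the other regroupings of libraries was 0 calls for shMed4 against NTC. The highest gave 48,518 against 79,398, in a split that kept the 3 NTC libraries together and mixed the hairpins only, so it still held the real contrast. The highest for both hairpins was 29,527 against 45,629. In each case 1 of 100 draws was as large, the real grouping, which excludes a random division of the libraries only. Libraries of a group resembled each other closely, so regrouping cannot exclude chance differences between the 3 groups of cells. The hairpin groups themselves differed at 61,001 peaks. A random division was not excluded for gene lists at gene ends, where 27 of 100 draws gave as many as the 2 lists called and the highest gave 8. Nor was it excluded for lists at other peaks, where 20 of 100 gave as many as the 1 called and the highest gave 1. For comparisons of 6 libraries the 10 splits are too few for a share under 0.05. The real counts of peaks were 77,395, 74,006 and 61,001 with 0 as the highest other (1 of 10 each). The real counts of lists were 2 and 4 with 4 and 6 as the highest others (2 and 4 of 10).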

How the results depend on the processing

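The removal of regional shifts, centring on gene-end peaks, thinning and lists without shared genes were chosen only after the result was seen. Counts of changed peaks stayed within 1.5 times the reported ones under every alternative but the demand for a log2 fold of at least 1, which by its construction left 10,176 peaks for shMed4 against NTC, 13,367 for hairpin #1, 11,807 for #4, 6,377 between the hairpins and 6,385 for both. Leaving out 1 library gave 68,586 to 80,779, 68,565 to 80,567, 64,736 to 74,424, 52,810 to 60,028 and 39,146 to 45,398. Shares of higher calls were 36.9% (centred away from gene ends) and 62.7% (on gene-end peaks) against 51.6%. For #1 they were 41.0% and 59.5% against 52.8%, for #4 36.1% and 66.4% against 51.9%, between the hairpins 43.7% and 56.7% against 49.0%, and for both 38.5% and 70.6% against 56.7%. Lists called at gene ends for shMed4 against NTC were 2 as reported, 4 with equal totals, 1 with cyclic loess, 0 with an estimated correlation, 0 without shared genes, 4 with regional shifts removed and 2 to 4 without 1 library (4 without #4 replicate 3). For #1 they were 2, 1 with cyclic loess, 0 with an estimated correlation and 0 to 2 without 1 library (0 without #1 replicate 1 or #4 replicate 3). For #4 they were 4, 1 with cyclic loess, 0 with an estimated correlation and 1 to 5 without 1 library (1 without #4 replicate 1). Lists at other peaks were 1, 0 with an estimated correlation and 0 with regional shifts removed. The cause was not tested. With gene ends taken as 2 kb, which by construction takes in more peaks, their shares were 9.2% of higher and 24.6% of lower peaks, and without 1 library 5.6% to 6.1% and 17.9% to 20.3%. For named peaks 0 values reversed, 64 were weaker, 60 of them by the log2 threshold, and 1 was stronger. Thinned to the shallowest library, 72,094 peaks were called for shMed4 against NTC, against 79,398 as reported. Which sizes of change were lost was not examined. Motif and GC content alternatives were not run.

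With the replicate number as a replicate block, 81,526, 79,653, 76,395, 63,631 and 47,512 peaks were called, and 2 lists in place of 4 for #4. Same-numbered libraries deviated together with correlations of -0.01 to 0.07, so the numbers were not taken as pairs.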

Other observations

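The definition of runs was fixed before the number expected by chance was seen, and the genes below were chosen only after the result was seen. Some gained peaks lay in clusters: the 108 runs of higher peaks held 1,229 of the 25,886 peaks higher with both hairpins. Among 2,119 genes that were nearest to at least 15 peaks, all 17 peaks nearest to Sash1, a signalling scaffold gene, rose with both hairpins (median log2 fold 2.79). The same held for all 18 peaks nearest to Pappa2 (1.55) and all 17 nearest to its paralog Pappa (1.44), both genes of proteases that cleave binding proteins of insulin-like growth factors. Of 17 peaks each, 14 rose at Csmd3 (1.74) and at the amino acid transporter gene Slc38a1 (1.35), 13 at the ubiquitin ligase gene Pdzrn3 (1.53) and 12 at Fbxl7 (1.43). Across all tested peaks 17.6% rose and 13.5% fell with both hairpins. The longest run was 41 peaks at Rbms3, on chromosome 9 from 116559894 to 117717831 (median 3.08). Others lay at Brinp3 (21 peaks, 2.79), the axon guidance receptor gene Robo2 (9 peaks, 2.55), the gelatinase gene Mmp2 (10 peaks, 2.21) and the glypican gene Gpc6 (30 peaks, 2.10).

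There were 27 runs of lower peaks, 16 of them on chromosome 2, against at most 3 in 100 shuffles. The lowest was at Gas7, on chromosome 11 from 67515484 to 67622759 (14 peaks, median -1.35). A pair of runs at the collagen gene Col5a1 on chromosome 2 held 11 and 12 peaks (-0.80 and -0.76). Their chi-square per degree of freedom was 1.6 and 1.5, against a median of 15.3 in ordinary stretches of 12 peaks, so a copy loss was not excluded there. Of 15 peaks nearest to Sod3, the extracellular superoxide dismutase gene, 11 fell (-0.59), and of 20 nearest to the endothelin receptor gene Ednra 12 fell (-0.58). With regional shifts removed 12 fell at each. At Ninl on chromosome 2, 16 of 18 fell, and 10 with regional shifts removed.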
